A study of Mchenga conophoros and Petrotilapia sp. 'chitimba' with 16 samples.

How the data were processed

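The series holds 16 RNA sequencing libraries from whole brains of 8 adult male fish, 4 Mchenga conophoros (MC) and 4 Petrotilapia sp. 'chitimba' (PC). Each fish gave total RNA (input) and RNA bound to ribosomes with phosphorylated protein S6, recovered by immunoprecipitation (IP) in the PhosphoTRAP method. Brains were collected 90 min after 15 min of mirror exposure or a control condition. The fish were processed in 2 batches (a with fish 9, 10, 11 and 12, b with fish 21, 22, 23 and 24), each with 1 fish per species and condition, so batch crosses the groups.

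The authors deposited a table of raw counts per assembled locus in each library, and per the file headers it carries the gene match of each locus. Per the submitters' processing notes cutadapt, HISAT2 and StringTie were used; their versions, their settings and the genome build are not given in the sources used here. The authors also deposited 3 DESeq2 result tables, with a log2 fold change and a p-value per locus, for IP against input, the mirror effect on it, and the species difference of that effect. Their model formula, test and filters are not stated. In these tables the adjusted p is listed as 100 for 24992, 42843 and 46414 of 61384 loci, which was read as missing, and the mean normalized count is never below 1.147, also for loci at 0 in every library. All statistics in the report were computed from the counts, and the deposited result tables were set beside them only in the closing section.

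Of 61384 loci, 7770 had 0 counts in all 16 libraries and 30487 matched an annotated gene by StringTie class code. Loci within introns (12751), unannotated loci (12042) and run-on fragments next to genes (4274) were kept. Loci took the symbol of the annotated gene they match. Sequence reads were not analysed here.

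The tests were run in R 4.3.3 with edgeR 4.0.16 (TMM normalization, filterByExpr with default settings on the 8 groups, quasi-likelihood F tests), limma 3.58.1, DESeq2 1.42.0 and the package data.table, version 1.17.8. The filter kept 29597 loci. The model had 1 coefficient for each of the 8 groups of species, condition and fraction, plus batch. The comparisons were IP against input, the mirror effect on IP enrichment, its species difference, the mirror effect on IP enrichment in MC and in PC, PC against MC in input, the species difference of IP enrichment, and mirror against control in IP and in input. All tests were two-sided, with p adjusted by Benjamini and Hochberg within a comparison and a threshold of 0.05. These comparisons, the gene lists, the rule for naming genes and the alternatives named in the next paragraph were fixed before the data were examined, and the report's order of presentation was not.

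The alternatives were the fish as a replicate block, limma-voom with the fish as a random effect, DESeq2 (Wald test), RLE size factors, no batch term, each batch alone, no low-count filter, at least 10 counts in at least 8 libraries, an adjusted p under 0.1, the 8 libraries of a fraction alone, and leaving out each fish. Input and IP of a fish share that fish per the labels, so the number pairs them; the correlation of their deviations from the group means over 856 loci was 0.16, 0.05, 0.51 and 0.22 in MC control, MC mirror, PC control and PC mirror fish. After the data had been seen, 3 choices were added: fits of the abundant loci alone (856 with a mean log2 CPM above 7), each alternative on the inputs or IP libraries alone (28742 loci for the inputs), and a fit without both MC fish of batch a. Size factors in the abundant-locus fits came from those loci. Group means of log2 CPM given beside a fold change were scaled to all tested loci over the 16 libraries. Beside fold changes from the abundant loci or from 1 fraction alone, their difference can thus depart from the fold change.

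Genes are named by rule: the 10 highest and 10 lowest log2 fold changes past the threshold with a symbol, a mean log2 CPM above 1 and all 8 fish of the same sign (or, between fish, no overlap of the groups). Where fewer than 10 passed, all were named with the 5 smallest p. The 4 members of each gene list with the smallest p, members that passed, and a fixed list of 34 single genes, of which 20 matched a symbol, were added. The text gives those most useful to a reader, and unnamed loci where they were the only ones called.

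The 24 gene lists covered immediate early genes, neuropeptides and precursors, steroid receptors and synthesis, monoamine genes, GABA and glycine neurons, glutamate neurons, pan-neuronal genes, radial glia and astrocytes, oligodendrocytes, microglia and macrophages, endothelial and mural cells, red blood cells, fibroblasts and meninges, pituitary hormones, photoreceptor and pineal genes, and skeletal muscle. They also covered ribosomal proteins, translation factors, mitochondrially encoded genes, nuclear respiratory chain genes, chaperones, the glucocorticoid and stress axis, social neuropeptide and hormone receptors, and synaptic plasticity and calcium signalling. Lists with at least 3 tested members were set against all other loci with camera (limma) on log2 CPM with a prior count of 2 and a preset correlation of 0.01. Alternatives were an estimated correlation, RLE scaling, a prior count of 0.5 and the fish block. Fry was also run, but it tests a list against no change and not against other loci. The lists were written from general knowledge of marker genes.

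A locus at 0 in every library on 1 side of a comparison was given a floor of 3 counts over that side, and its fold change is then a bound. Where only 1 group of 2 fish on a side was at 0, the report gives counts in place of a fitted fold change, and the closing section a bound from 3 counts over that group. Library measures were compared with exact permutation tests. The number of distinct RNA molecules behind a library was estimated as the number of independent draws from the mean input composition that gives the number of loci detected: 31560 on average for IP and 846200 for input, against 6541000 and 13860000 counts. Depth per library is given in the report.

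The pipeline was tested on simulated data made from mean compositions of the real libraries. Runs with the spread of the input libraries used the mean input composition. Runs with the spread measured in each fraction used the mean of both fractions for IP against input, and each fraction's own mean otherwise. The spread was estimated without species, condition or batch, so it includes their differences. With the spread of the input libraries everywhere, IP against input gave 5 false calls among 139 and recovered 89.6% of 4-fold changes. With the spread measured in each fraction it gave 12908 false calls among 12995 (12886 of them lower in IP), and 13 among 29 in the abundant loci. PC against MC in the inputs alone gave 25 false calls among 103 and recovered 0%, 37.3% and 80.3% of 2-, 4- and 8-fold changes; over all 16 libraries it recovered 0% at each size. DESeq2 on the inputs alone gave 158 false calls among 278, and mirror against control in the inputs alone 66 among 164.

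Real groupings were compared with other splits: 100 splits of the 16 libraries, 100 swaps of IP and input within fish, and all 35 splits of the 8 fish, fitted with batch and without condition. DESeq2 splits used 1 in 8 of the tested loci. Trends on locus length were fitted with a span of 0.3, with 10000 length-matched lists, and 1000 bootstraps were drawn for the carry-over test.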

Results

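RNA from whole brains of 8 adult male cichlid fish was sequenced, 4 of Mchenga conophoros (MC) and 4 of Petrotilapia sp. 'chitimba' (PC), species that the series describes as differing in their aggression towards a mirror. In each species, 2 fish had faced a mirror in the home tank for 15 min, where the reflection stands in for a rival, and 2 were controls. The brains were collected after 90 min. Each brain gave 2 libraries: total RNA (input), and RNA recovered with an antibody against phosphorylated ribosomal protein S6 (IP). Phosphorylation of S6 rises in active neurons, so this method, PhosphoTRAP, is used to enrich ribosome-bound RNA of cells that were recently active. The 16 libraries form 8 groups of 2 fish, and each of the 2 batches (a and b) holds 1 fish of every species and condition.

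The input libraries of MC held 10665038 and 10073251 counts in control fish 10 and 22, and 10456641 and 10904974 in mirror fish 9 and 21. Those of PC held 10940859 and 12190271 in control fish 11 and 24, and 22058698 and 23594320 in mirror fish 12 and 23. The IP libraries of the same fish, in the same order, held 2715091, 9263533, 1872019, 9147304, 6969612, 4250470, 6920110 and 11186928 counts. Of 61384 assembled loci, an input library detected 33230 ± 1405 (mean ± SD, n = 8) and an IP library 7766 ± 2581 (n = 8). IP libraries detected fewer in 8 of 8 fish (exact sign-flip test, two-sided, p = 0.00781, the smallest this design can give; adjusted p = 0.0614 over 55 tests of library measures). Of 17575 loci with counts in all 8 inputs, 3633 had 0 counts in all 8 IP libraries. A count of 0 allows up to 0.268 to 1.60 CPM (counts scaled to library size) in an IP library and 0.127 to 0.298 CPM in an input library, from a floor of 3 counts. These floors, and every bound below, cover counting error only. They treat counts as independent, but an IP library held 92.9 to 508 counts per estimated RNA molecule and an input library 8.96 to 41.4. By this estimate a single missed molecule can stand for many counts, and bounds from 0 counts, above all in IP, overstate the differences that the data can establish. The estimate takes an IP library to have the mean input composition, so a real difference between the fractions can shift it. Every IP library detected fewer loci than it predicts at 100 to 300 CPM in input and more at 1 to 3 CPM. In MC control fish 10 these were 60.67% against 84.65% and 6.14% against 2.23%. Duplicate reads were not examined. The median correlation of log2 CPM between libraries was 0.79 among inputs and 0.44 among IP libraries.

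**Figure D1:**
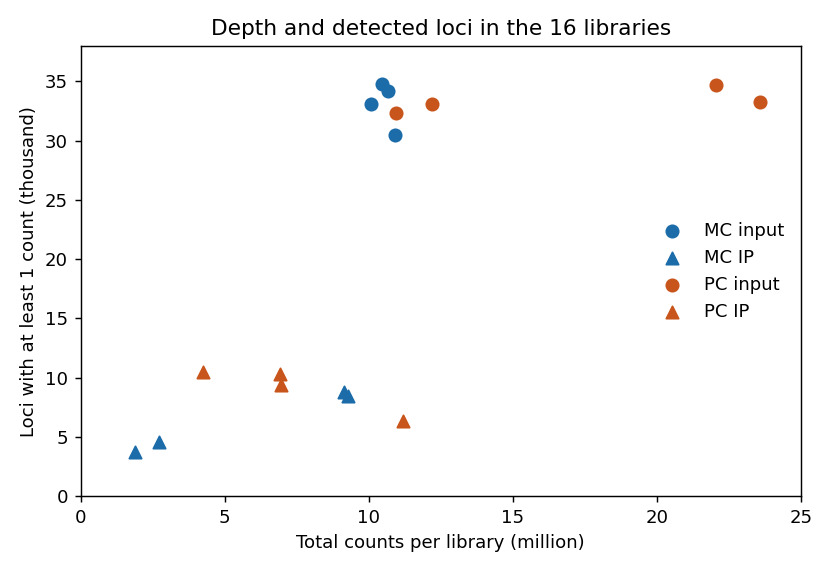
Total counts per library (x axis) against the number of loci with at least 1 count (y axis) for the 8 input (circles) and 8 IP libraries (triangles) of MC (blue) and PC (orange). The inputs detect 30469 to 34760 loci and the IP libraries 3714 to 10466, also at similar totals.

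The first comparison set IP against input, to ask which transcripts were carried on phosphorylated ribosomes. It is described first for 856 abundant loci (mean log2 CPM above 7), a set chosen after the counts had been seen because most other loci were at 0 in most IP libraries. Transcripts of the mitochondrial genome, which are translated inside mitochondria and not by S6-containing ribosomes, fell the most as a group. All 8 measured members were lower in IP in 8 of 8 fish, among them ND5 (8.74 ± 1.46 against 13.02 ± 0.90 log2 CPM, SD, n = 8; log2 fold change -4.14 ± 0.46 SE, adjusted p = 5.42e-04). Others were ND2 (-3.19 ± 0.27, adjusted p = 4.40e-04) and COX1 (-1.85 ± 0.23, adjusted p = 8.68e-04). Glial transcripts fell as well: the glutamate transporter gene slc1a2 (-3.48 ± 0.76, adjusted p = 0.0110), the calcium-binding protein gene s100b (-2.27 ± 0.29) and the fatty acid-binding protein gene fabp7 (-1.18 ± 0.15), each lower in 8 of 8 fish. Other transcripts lower in 8 of 8 fish were the myelin gene mpz (-3.76 ± 0.68), the antigen-presentation gene cd74 (-3.76 ± 0.78) and the lysosomal gene psap (-4.02 ± 0.53). So were aplp2 (-3.72 ± 0.56), and atp1b4 (adjusted p = 0.00388), fez1 (adjusted p = 0.00743), lg8h10orf88 (adjusted p = 0.0180) and srgn (adjusted p = 5.42e-04), which had 0 counts in both IP libraries of MC control or, for fez1, MC mirror fish, so that no fold change is given. The calls of cd74 and lg8h10orf88 were lost without any 1 of the 4 PC fish, that of fez1 without PC fish 11, 24 or 23, and those of slc1a2 and atp1b4 without PC control fish 24; without MC control fish 22 cd74 was at -6.37.

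Transcripts that rose in IP in 8 of 8 fish included chd2, which encodes a chromatin remodeller (10.29 ± 1.22 against 7.93 ± 0.47 log2 CPM, SD, n = 8; log2 fold change 2.52 ± 0.36, adjusted p = 0.00131). The same held for the proteasome gene psmc3 (2.47 ± 0.36), hdgfl2 (2.35 ± 0.35), the RNA decay gene upf2 (2.03 ± 0.34), rnf208 (1.96 ± 0.19) and rab3c, of synaptic vesicles (1.92 ± 0.34). Translation initiation genes rose, namely eif5b (1.85 ± 0.26), eif3j (1.70 ± 0.33), eif2s2 (1.36 ± 0.23) and eif5a (1.19 ± 0.22), while eef1g (-1.10 ± 0.20) and naca (-0.41 ± 0.12, 6 of 8 fish) fell. Nuclear genes of the respiratory chain that rose were atp5mf (1.56 ± 0.15, adjusted p = 4.87e-04), ndufa1 (1.56 ± 0.21), ndufa2 (1.26 ± 0.19), ndufc1 (1.57 ± 0.33, 7 of 8 fish) and atp5f1e (1.17 ± 0.16, 7 of 8 fish). The pan-neuronal genes went both ways: sncb rose (0.99 ± 0.27, 7 of 8 fish), and snap25 (-1.24 ± 0.34), rtn1 (-1.49 ± 0.44) and nefm (-1.52 ± 0.45, 7 of 8 fish) fell. The GABA receptor gene gabrd (1.40 ± 0.39) and chgb, of secretory granules (1.02 ± 0.32, 6 of 8 fish), rose. The chaperone gene hsp90ab1 (-1.22 ± 0.22), the calcium pump gene atp2b2 (-2.69 ± 0.64, 7 of 8 fish) and the myoglobin gene mb (-2.43 ± 0.60, 7 of 8 fish) fell. The transcript of S6 itself, rps6, did not pass (0.14 ± 0.22, adjusted p = 0.692), nor did npy (-1.57 ± 0.56, adjusted p = 0.0705). Several of these calls were lost often under 16 alternatives: naca in 12 (-0.49 to -0.19), nefm in 11 (-2.20 to -1.06), gabrd in 9 (1.14 to 1.88), chgb (0.35 to 1.83), sncb, snap25 and rtn1 in 8 each, atp2b2 in 7, and mb and ndufc1 in 5 each. Leaving out any 1 PC fish was enough for naca, gabrd, chgb, sncb, snap25, rtn1 and atp2b2, and PC fish 11, 24 or 23 for nefm and ndufc1. So was MC control fish 10 for naca, nefm, sncb and snap25, MC control fish 22 for nefm, gabrd, chgb, sncb and snap25, MC mirror fish 9 for naca and rtn1, and MC mirror fish 21 for nefm, gabrd and chgb. The call of mb was lost without PC fish 11, 24 or 12 (-3.71 without MC mirror fish 21), that of hsp90ab1 without PC mirror fish 23 and that of eef1g without PC control fish 24.

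Gene lists fixed before the data were examined were set against the other abundant loci with camera (limma). The median log2 fold change of all 856 loci was -0.31. Mitochondrially encoded genes had a median of -2.72 with 8 of 8 lower (8 adjusted over the list alone; list adjusted p = 1.69e-05, adjusted p = 0.275 with an estimated correlation). Their median was -2.29 in batch a alone and -2.55 in batch b alone. Over all loci, the comparison named beforehand, this list and the radial glia list did not pass. In the radial glia and astrocyte list 3 of 5 fell (3 adjusted over the list alone), with a median of -1.18 (list adjusted p = 0.0485; adjusted p = 0.327 with an estimated correlation and 0.0562 with fish as a block). Of 30 nuclear respiratory chain genes 8 rose and 0 fell (9 and 0 adjusted over the list alone; list adjusted p = 0.0314, adjusted p = 0.596 with an estimated correlation). Their median was 0.15, but -0.19 with fish as a block and -0.18 with limma-voom. Of 13 translation factors 4 rose and 2 fell (5 and 2 adjusted over the list alone), with a median of 0.09 (list adjusted p = 0.0485; adjusted p = 0.338 with an estimated correlation and 0.0562 with fish as a block). Ribosomal protein genes had a median of -0.27. Among 3 of 67 that rose were rps29 (0.64 ± 0.14, 5 of 8 fish) and rps24 (0.53 ± 0.14, 6 of 8 fish), and among 11 that fell was rplp0 (-1.04 ± 0.30, 8 of 8 fish; the same numbers adjusted over the list alone; list adjusted p = 0.487). The call of rplp0 was lost in 10 of 16 alternatives, among them without MC mirror fish 9 or 21 or any 1 PC fish, that of rps24 without PC fish 24, 12 or 23 and that of rps29 without PC control fish 24. The pan-neuronal list (1 of 10 higher and 3 lower; 1 and 3 adjusted over the list alone) had a median of 0.12 and a mean of -0.20, and did not pass (list adjusted p = 0.487).

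**Figure D2:**
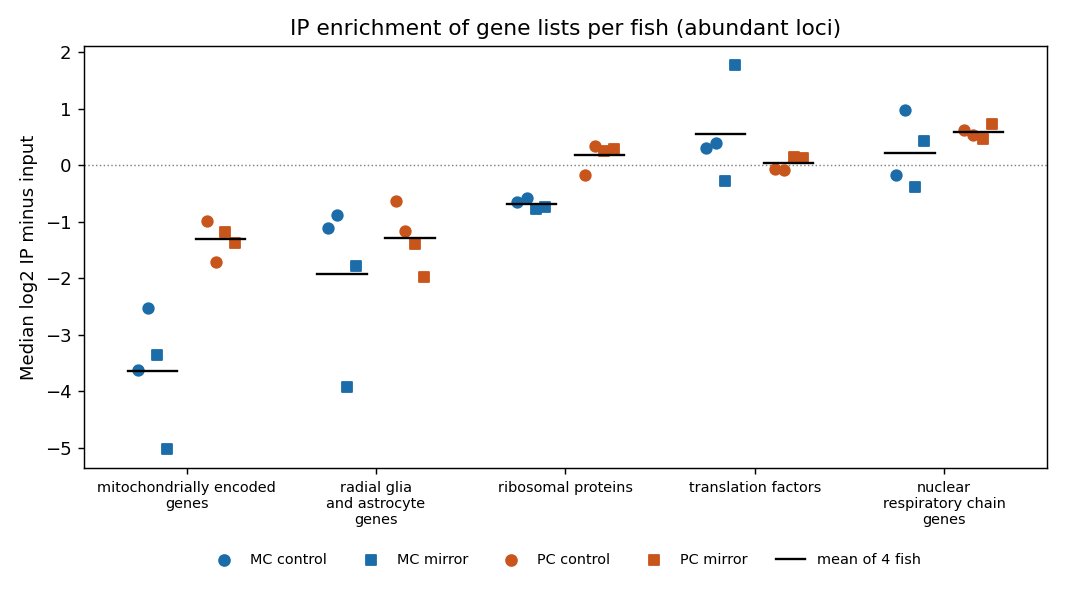
Median log2 IP minus input (y axis) of 5 gene lists among the abundant loci, per fish, for MC (blue) and PC (orange), with control fish as circles, mirror fish as squares and the mean of 4 fish as a line. Mitochondrially encoded genes lie at -5.03 to -2.53 in MC and at -1.71 to -0.99 in PC.

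Over these 856 loci edgeR called 91 higher and 108 lower in IP (199 in all; 333 by DESeq2, and 129 higher and 247 lower by limma-voom). Simulated data with the spread measured in each fraction gave 13 false calls among 29 in these loci, 12 of them lower. With fish as a replicate block, 45 were higher and 61 lower. Batch a alone gave 0 by edgeR (130 at an unadjusted p under 0.05) and batch b alone 80. Without MC control fish 22 or MC mirror fish 21 the count rose to 299 or 303. Without PC control fish 24, PC control fish 11, PC mirror fish 23 or PC mirror fish 12 it was 91, 98, 102 or 131.

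Over all 29597 tested loci, the comparison named before the data were examined, 98 loci were higher and 16997 lower in IP, with a median log2 fold change of -4.97. Among the lower loci, rogdi, pef1, stk24, limch1 and rchy1 had counts in every input and 0 in all 8 IP libraries, so their log2 fold changes are bounds against 3 counts over the group. By this floor of counts they lay at least 9.39, 9.18, 9.09, 8.96 and 8.83 below input. A floor in molecules, as estimated above, would bring these bounds much nearer to input. The synaptic scaffold gene cnksr2 was higher (2.98 ± 0.64, adjusted p = 0.00346). Relative to other loci, endothelial and mural genes were lower (16 of 17, the same number adjusted over the list alone; median -7.13, list adjusted p = 0.0205). Ribosomal protein genes (median -0.38, list adjusted p = 8.69e-11), nuclear respiratory chain genes (-0.46, 8.69e-11), pan-neuronal genes (-1.35, 3.37e-05) and translation factors (-1.57, 3.90e-04) lay above the median of all loci. For all 5 lists the adjusted p was 0.431 or more with an estimated correlation. Abundant members numbered 0 of 17 endothelial, 67 of 67 ribosomal, 30 of 43 respiratory, 10 of 19 pan-neuronal and 13 of 37 translation factor genes. Most loci that are not abundant were at 0 in most IP libraries. The place of a list over all loci may thus follow the abundance of its members, and these tests cannot tell that from enrichment. Members called lower and adjusted over the list alone numbered 0 of 67 ribosomal protein genes, 7 of 43 respiratory genes, 3 of 19 pan-neuronal genes and 10 of 37 translation factors. Members called higher in this way numbered 0, 6, 0 and 4. The mitochondrially encoded list did not pass (8 of 8 lower, 8 adjusted over the list alone; median -2.82, list adjusted p = 0.0923, 0.193 with RLE scaling, 0.3286 with a prior count of 0.5 and 0.145 with fish as a block). Nor did the radial glia and astrocyte list (9 of 14 lower, 9 adjusted over the list alone; -3.24, 0.757). Camera placed both lower than other loci, while their fitted medians lay above that of all loci. Data simulated with no difference for most loci and the spread measured in each fraction gave 12908 false calls among 12995, and DESeq2 called 15589 loci. With fish as a replicate block 8 loci were higher and 173 lower. Batch a alone gave 7335 and batch b alone 5136. The fit without both MC fish of batch a, whose IP libraries held the fewest counts, gave 4, but 8747 at an adjusted p under 0.1 and a median of -3.95 over 37628 loci, and the fits without MC mirror fish 9 or 21 gave 9582 and 11335.

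The next comparison asked whether IP enrichment differed between the species. Mitochondrially encoded transcripts were depleted less in PC than in MC. The log2 difference of IP minus input for ND2 was -1.10 ± 0.68 in PC and -5.63 ± 3.38 in MC (SD, n = 4 each; fitted species difference 4.52 ± 0.54 SE, adjusted p = 0.0367). That for ND1 was -0.49 ± 0.42 and -3.24 ± 0.91 (2.66 ± 0.35, adjusted p = 0.0367), and that for COX1 -0.93 ± 0.27 and -3.10 ± 0.94 (2.12 ± 0.27, adjusted p = 0.0367; 1.80 ± 0.46 and not passing among the abundant loci, adjusted p = 0.0999). In MC mirror fish 9 and 21 the IP libraries held 44 and 110 counts of ND2, against 1717 and 11151 in MC control fish 10 and 22. Transcripts of srgn, a proteoglycan gene of blood cells, lg7h18orf32 and the lysosomal gene laptm4a were found in every PC IP library and almost none of MC. For srgn MC held 0, 0, 3 and 9 counts and PC 709 to 5091. For lg7h18orf32 MC held 0 in all 4 and PC 799 to 2572, a log2 difference in enrichment of at least 10.11. For laptm4a, also with 0 in all 4 MC libraries, it was at least 9.98.

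Ribosomal protein genes also differed. The median species difference was 0.92 over all loci and 0.31 over the abundant ones. Among the abundant loci their median species difference was 0.97 (2 of 67 higher and 0 lower, 9 and 0 adjusted over the list alone; list adjusted p = 1.90e-08, adjusted p = 0.147 with an estimated correlation). Among them were rpl39 at 2.61 ± 0.44 (adjusted p = 0.0149) and rps15 at 1.17 ± 0.24 (adjusted p = 0.0465), both lost without MC control fish 10, MC mirror fish 9 or any 1 PC fish. Mitochondrially encoded genes had a median of 2.52 (2 of 8 higher, 8 adjusted over the list alone; list adjusted p = 7.11e-06, adjusted p = 0.147 with an estimated correlation). It was 2.47 in batch a alone and 2.18 in batch b alone. Translation factors had a median of -0.51 (0 of 13 called, 0 adjusted over the list alone; list adjusted p = 0.0337, adjusted p = 0.257 with an estimated correlation). Their medians per fish overlapped (0.30, 0.40 and -0.29 in MC, 1.77 in MC mirror fish 21, -0.08 to 0.15 in PC), so the difference per fish rests mostly on fish 21, although the fitted median was -0.41 without it. The retinol carrier gene rbp4 was recovered in PC IP libraries (462 to 1878 counts) and almost absent from those of MC, with counts of 0, 3, 0 and 3 (fitted log2 difference 9.88 ± 1.19, adjusted p = 0.00235). The size of this difference rests on those few MC counts. With all loci, mitochondrial genes (3 of 8 called, 8 adjusted over the list alone; list adjusted p = 1.53e-05), ribosomal protein genes (0 of 67, 0 adjusted over the list alone; 2.65e-08) and nuclear respiratory chain genes (0 of 43, 2 adjusted over the list alone; 0.0210) passed. For each the adjusted p was 0.909 with an estimated correlation.

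In all, edgeR called 11 loci higher and 0 lower over all loci (2447 at an unadjusted p under 0.05; 2544 by DESeq2, 136 by limma-voom) and 15 higher and 0 lower among the abundant ones (129; 101 by DESeq2, 54 by limma-voom). With fish as a replicate block there were 26 and 0, in batch a alone 0 and 79, and in batch b alone 0 and 0. All-locus calls fell to 3 without MC control fish 10 and to 0 without MC mirror fish 9, MC mirror fish 21 or any 1 of the 4 PC fish. The abundant-locus count fell to 0 without PC fish 11, 24 or 23, and was 133 without MC control fish 22, 129 without MC mirror fish 21 and 24 without MC mirror fish 9. Without both MC fish of batch a the counts were 1 and 63. The IP libraries of MC had fewer counts on the mitochondrial sequence than those of PC (3.58 ± 0.703% against 8.66 ± 3.85%, SD, n = 4 each; exact permutation test, two-sided, p = 0.0286, the smallest possible; adjusted p = 0.121 over 55 tests).

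The mirror comparisons asked which transcripts of active cells followed the mirror test, and whether the response differed between the species. LOC101486506, a gene without a name, stood out: MC control IP libraries held 1768 and 1400 counts and both MC mirror IP libraries 0, while PC held 3784 to 15819. Its IP enrichment fell with the mirror in MC by a log2 value of at least 9.60 (adjusted p = 0.0122), and mirror against control in IP over both species passed for it (adjusted p = 0.00907), which rests on the MC mirror libraries at 0. In PC the mirror effect on its enrichment was -0.26 ± 0.91 (adjusted p = 1). Over all loci it did not pass for the mirror effect on enrichment over both species (adjusted p = 0.0578) or for the species difference of that effect (adjusted p = 0.0781); among the abundant loci it passed for both (adjusted p = 0.0371 and 0.0364). Among the abundant loci, ND2 enrichment fell with the mirror in MC (-5.59 ± 0.74, adjusted p = 0.00812) and the species difference of the effect passed (5.83 ± 1.00, adjusted p = 0.0457). Both calls were lost without any 1 PC fish, and the second also without MC control fish 10 or MC mirror fish 9. Over all loci it did not (6.15, adjusted p = 0.677). The median IP minus input of the 8 mitochondrially encoded genes did not fall with the mirror in both batches of MC. In batch a it was -3.36 in mirror fish 9 and -3.63 in control fish 10. In batch b it was -5.03 in mirror fish 21 and -2.53 in control fish 22. A mirror effect on ND2 is thus not shown for these genes as a group. The IP transcripts of sertm1, the nucleolar gene fbl and sgtb had 0 counts in all 4 mirror fish and 155 to 1631, 111 to 1031 and 37 to 440 in the 4 control fish. Their log2 bounds were at least 10.28, 9.75 and 9.02 below control, but the adjusted p was 0.205, 0.305 and 0.305.

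The counts of loci were small in edgeR and large in DESeq2. For the mirror effect on IP enrichment edgeR called 0 (1556 at an unadjusted p under 0.05; limma-voom 0, DESeq2 1821) and for its species difference 0 (1711; 0 and 1992). It called 1 in MC, LOC101486506 (2751; 0 and 2071), and in PC 0 (2806; 0 and 1201). With fish as a replicate block these were 4, 4, 6 and 2, and the first was 0 in each batch alone. Mirror against control within IP gave 1 lower locus, again LOC101486506 (2401; limma-voom 174, DESeq2 2990; 0 in each batch alone), and 10 from the 8 IP libraries alone (277 at an unadjusted p under 0.05; 871 by DESeq2). Without a batch term edgeR called 0 from these 8 (827). Without MC control fish 22, MC mirror fish 21, PC control fish 11 or PC mirror fish 12 it called 29, 19, 6 or 5, with 17267 to 17838 loci tested in place of 10304. Among the abundant loci edgeR called 2, 4, 7, 0 and 6 for these 5 comparisons, in the same order (45, 54, 81, 6 and 106 at an unadjusted p under 0.05). Limma-voom called 0 for each of the 5 and DESeq2 37, 35, 64, 2 and 92. With RLE size factors edgeR called 0, 3, 6, 0 and 6, and with fish as a block the first 4 were 0. From the IP libraries of the abundant loci alone it called 0 for the last (26). Without MC mirror fish 21 these rose to 106, 103, 124, 0 and 154, and without PC control fish 11 they were 0, 0, 0, 0 and 0. The call of LOC101486506 in MC was lost without 1 fish in several cases, with 0 loci called without MC mirror fish 9 or 21 or any PC fish. Of the gene lists, ribosomal protein genes passed among the abundant loci for the mirror effect on enrichment in PC (median 0.14, 0 of 67 called, 0 adjusted over the list alone; list adjusted p = 0.0229, adjusted p = 0.485 with an estimated correlation) and for mirror against control in input (0.09, 0 of 67, 0; 1.12e-05, 0.615). On simulated data with the spread of each fraction, 0% of loci changed 8-fold were recovered for the mirror effect on enrichment. That spread was estimated without species, condition or batch, so it includes their differences and may understate recovery.

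Immediate early genes, which neurons switch on within minutes of activity, were nearly out of reach in IP. Of 26 tested, 22 had counts in 4 or fewer of the 8 IP libraries and 5 in none, and fosl2 and scg2 had counts in all 8. In input, npas4 was at 4.48 ± 0.42 log2 CPM in mirror fish and 5.51 ± 0.60 in control fish (SD, n = 4 each; log2 difference -1.06 ± 0.22 in the inputs alone, adjusted p = 0.547), and egr1 at 6.01 ± 0.33 and 5.84 ± 0.59. The list did not pass in the inputs alone (0 of 26 called, 1 lower adjusted over the list alone; list adjusted p = 0.428). Mirror against control in input gave 0 loci over all 16 libraries (320 at an unadjusted p under 0.05; 36 by DESeq2, 0 by limma-voom) and 1 higher and 2 lower from the inputs alone (1170; 139 by DESeq2). These were the unnamed loci MSTRG.42415 (lower, adjusted p = 0.0225), MSTRG.19476 (-4.32 ± 0.42, adjusted p = 0.0347) and MSTRG.50064 (higher, adjusted p = 0.0286). MSTRG.50064 had 0 counts in the 2 MC control inputs and 5077 to 22766 in the other 6. MSTRG.42415 had 0 in the 2 MC mirror inputs and 349 to 1076 elsewhere. Without the low-count filter there were 272. Leaving out 1 fish gave 62 (MC control fish 10) to 491 (MC mirror fish 9), but also let 37060 to 40991 loci through the filter in place of 28742.

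The last comparison set PC against MC in input, that is, in total brain RNA. In the 8 input libraries alone, nuclear genes of the respiratory chain were higher in PC: 41 of 43 rose and 1 fell (the same numbers adjusted over the list alone). Examples were ndufa5 (9.92 ± 0.33 against 8.48 ± 0.48 log2 CPM, SD, n = 4 each; 1.74 ± 0.17 SE, adjusted p = 8.55e-04), ndufb4 (1.72 ± 0.19), ndufa1 (1.72 ± 0.22) and atp5mf (1.53 ± 0.17). The exception was sdha (-1.43 ± 0.24). With the trend of the fold changes on locus length removed, the median of the list went from 1.68 to 0.66. With the inputs scaled to the abundant loci alone, ndufa5 kept 0.82 ± 0.11, ndufb4 0.80 ± 0.13, ndufa1 0.81 ± 0.19 and atp5mf 0.61 ± 0.12, and all 4 passed. Of 24 neuropeptide and precursor genes 6 were higher and 1 lower. Those higher were npy (7.95 ± 0.49 against 6.03 ± 0.88; 2.13 ± 0.31, adjusted p = 0.00352), gnrh1 (3.31 ± 0.52), gnrh2 (adjusted p = 0.0125; 0 counts in the 2 MC mirror inputs, 16 and 25 in MC control and 40 to 123 in PC), cck (1.26 ± 0.22), chga (1.07 ± 0.18) and rln3, and scg3 was lower (-0.79 ± 0.20). Under that scaling npy kept 1.23 ± 0.33 (adjusted p = 0.0265), scg3 was at -1.69 ± 0.20 and chga did not pass (0.16 ± 0.16, adjusted p = 0.428). The call of scg3 was lost without MC control fish 22, PC control fish 11 or PC mirror fish 23, and that of rln3 without MC control fish 10 or 22, PC control fish 24 or PC mirror fish 23. The relaxin family gene rln3 had 0 counts in the 4 MC inputs and 5 to 91 in PC, at least 32.0-fold higher. Genes of radial glia, fabp7 (1.73 ± 0.15, adjusted p = 6.84e-04) and s100b (1.33 ± 0.14), and the kinase gene camk2a (2.43 ± 0.25) were higher in PC. Scaled to the abundant loci, fabp7 kept 0.81 ± 0.13 (adjusted p = 0.00458) and s100b did not pass (0.41 ± 0.15, adjusted p = 0.0564). Single genes lower in PC were the receptor genes grin2b (adjusted p = 0.00375), glra1 (-1.54 ± 0.34) and grm8 (-1.23 ± 0.26), sv2a of synaptic vesicles (-1.29 ± 0.19) and the myelin gene mag (-1.01 ± 0.18, and -1.92 ± 0.15 scaled to the abundant loci). The call of glra1 was lost without MC control fish 10 or PC mirror fish 12, and that of grm8 without MC control fish 22 or PC control fish 11. The thyroglobulin gene tg had 0 counts in all 4 PC inputs and 34 to 127 in MC, at least 148-fold lower in PC.

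Other genes chosen by size of change were psmd8 (adjusted p = 0.00101) and rnf25 (adjusted p = 8.84e-04), both higher in PC with 0 counts in the 2 MC mirror inputs, and rmnd1, with 0 counts in MC and 15 to 117 in PC (at least 42.8-fold higher). Lower in PC were dolpp1 (-4.85 ± 1.17; -8.21 without PC mirror fish 12 and -7.31 without PC control fish 24), ifrd1 (-2.89 ± 0.30), stk40 (-2.63 ± 0.44) and eps8l2 (-2.34 ± 0.26). Immediate early genes called higher were dusp5 (1.65 ± 0.27), ier2 (1.82 ± 0.38) and gadd45b (0.97 ± 0.25), 3 of 26 (3 adjusted over the list alone; list adjusted p = 0.224). The call of gadd45b was lost without MC control fish 10, PC control fish 11 or PC mirror fish 12, that of ier2 without PC control fish 24 and that of rmnd1 without PC mirror fish 23. Of the mitochondrially encoded genes CYTB (1.54 ± 0.13) and ND2 (1.06 ± 0.13) were higher and ND6 (-1.47 ± 0.28) lower, 3 of 8 in all (2 and 2 adjusted over the list alone; list adjusted p = 0.999). Scaled to the abundant loci, CYTB was at 0.62 ± 0.14 (adjusted p = 0.0135), ND2 at 0.14 ± 0.14 (adjusted p = 0.407) and ND6 at -2.40 ± 0.34 (adjusted p = 0.00360). ND2 did not pass without a batch term either (adjusted p = 0.0746).

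Of 4 lists that passed camera in these inputs, the nuclear respiratory chain list had a median of 1.68 (list adjusted p = 1.10e-15; adjusted p = 0.779 with an estimated correlation). Of 67 ribosomal protein genes 60 were higher and 0 lower (63 and 0 adjusted over the list alone), with a median of 0.86 (list adjusted p = 4.82e-12; adjusted p = 0.871 with an estimated correlation). The median turned to -0.06 when the inputs were scaled to the abundant loci alone. Without a batch term 2 of 67 passed, with a median of 0.81. Among the genes called was rps6 (1.32 ± 0.14; 0.41 ± 0.08 under that scaling). Of 37 translation factors 17 were higher and 0 lower (22 and 1 adjusted over the list alone), such as eif1ax (1.54 ± 0.18; 0.63 ± 0.16 under that scaling) and naca (1.24 ± 0.15; 0.31 ± 0.10). Their median was 0.73 (list adjusted p = 1.59e-04; adjusted p = 0.779 with an estimated correlation), and -0.02 for the 13 abundant members in the fit of abundant loci. Of 24 neuropeptide genes 6 were higher and 1 lower (10 and 1 adjusted over the list alone). Their median was 1.57 (list adjusted p = 4.03e-04; adjusted p = 0.779 with an estimated correlation), and -0.24 for the 4 abundant members under that scaling. The 30 abundant respiratory members had a median of 0.85 under that scaling, with 28 higher. The pan-neuronal list did not pass (4 of 19 higher and 1 lower, 5 and 3 adjusted over the list alone; median -0.02, list adjusted p = 0.984). Nor did the radial glia and astrocyte list or the glutamate neuron list, which hold some of the single genes named above.

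**Figure D3:**
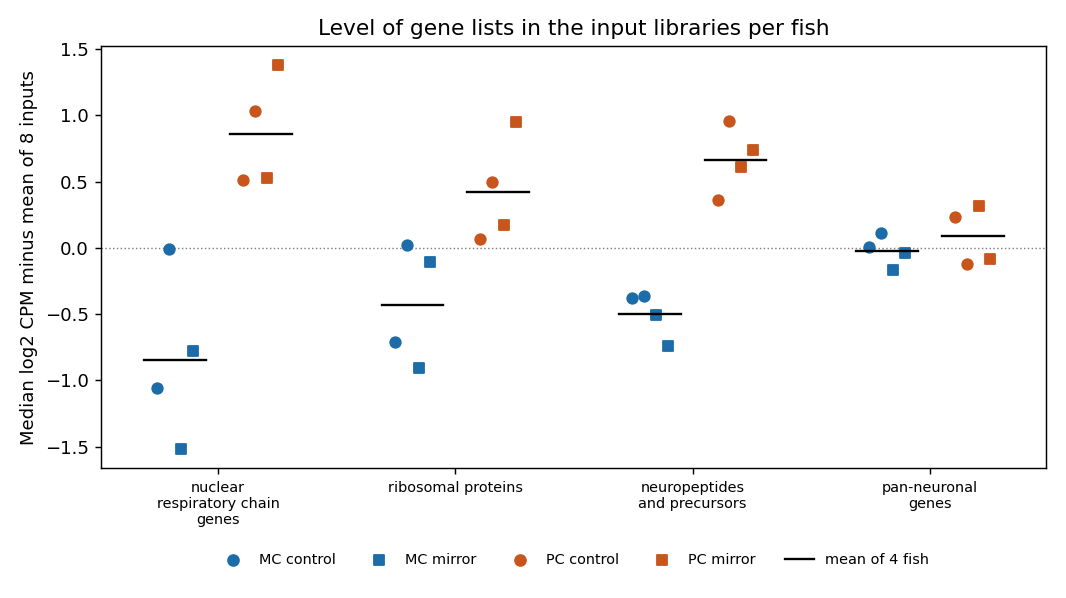
Median log2 CPM of 4 gene lists in each input library minus the mean of the 8 inputs (y axis), per fish, for MC (blue) and PC (orange), with control fish as circles, mirror fish as squares and the mean of 4 fish as a line. Nuclear respiratory chain genes lie at 0.51 to 1.38 in PC and at -1.52 to -0.01 in MC; in the fit of abundant loci alone, the difference is -0.06 for ribosomal protein genes and -0.24 for the 4 abundant neuropeptide genes.

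In the inputs alone edgeR called 2345 loci higher and 655 lower in PC (7320 at an unadjusted p under 0.05). DESeq2 called 3633 higher and 2285 lower, edgeR on the loci matching an annotated gene 1712 and 857, and edgeR on the 856 abundant loci alone 279 and 257. Without MC mirror fish 9, where 37846 loci were tested in place of 28742, there were 5406 calls. Over all 16 libraries, the fit named before the data were examined, it called 0 (2068; 425 by limma-voom, 115 by DESeq2; 0 in each batch alone), and the 3 smallest p belonged to MSTRG.35831, gabarap (2.99 ± 0.40) and LOC101469063, each with an adjusted p of 0.104. MSTRG.35831 had 0 counts in PC inputs and 4781 to 5497 in MC, at least 11210-fold lower in PC. LOC101469063 had 0 in MC and 2520 to 6243 in PC, at least 3447-fold higher. For these loci, and for rln3, rmnd1 and tg, 0 counts in 1 species may reflect the fit of its reads to the shared reference and not expression. That was not tested. The PC inputs were deeper (17200000 ± 6552000 against 10520000 ± 352500 counts, SD, n = 4 each; exact permutation test, two-sided, p = 0.0286, adjusted p = 0.121 over 55 tests). They held fewer counts at loci inside introns (0.642 ± 0.0874% against 1.70 ± 0.379%; exact permutation p = 0.0286, adjusted p = 0.121). Among annotated loci the median log2 difference was 1.09, 0.64, 0.32, 0.11 and -0.10 in 5 equal bins from the shortest to the longest loci. The fold changes of single genes in input were not corrected for this trend, so a part of them may follow locus length.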

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

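The 2 tests of locus length alone, the 2 tests of scaling to the abundant loci and the DESeq2 splits for the species difference of IP enrichment, PC against MC in input and mirror against control in IP and in input were chosen after their results had been seen, and the fits of abundant loci after the data had been seen. The bounds of the other tests were written before their values were known, but the predicted shift of 0.86 given for carry-over was not among them. Dixon's test was applied to 86 sets of 4 to 8 values and marked 5 of them, where chance gives about 1 in 20 (4.3).

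The first pattern is that most loci were lower in IP than in input. The 20471 nuclear loci at 1 to 30 CPM in input held 0.766 ± 0.217 of their input share in IP (SD, n = 8, range 0.487 to 1.12), although only 17.4% of them had counts in a given IP library. A bound of 0.67 or more had been set for sparse sampling of RNA molecules, so this may explain most of the 16997 lower loci; those loci themselves kept 0.406 of their share, but were selected for being low, and mitochondrial loci kept 0.249. Of 100 splits of the 16 libraries 1, the real one, gave as many calls (13152, against 3976 in the highest other). The 2 fractions thus differ beyond chance as libraries. Whether single loci differ is not shown by this count, as simulated data with no difference for most loci gave 12908 false calls. Among the abundant loci the real split was also the only 1 of 100 with as many calls (112 against 1), and swaps within fish gave at most 1. A biological explanation, that phosphorylated ribosomes carry fewer mitochondrial and glial transcripts, stays open for the abundant loci.

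The second pattern is that mitochondrially encoded transcripts were less depleted from IP in PC than in MC, which came from tests of the difference between the species. If more input RNA had been carried into PC IP libraries, the 126 nuclear loci depleted in both species in batch a would shift by 0.86 in batch b, while the mitochondrial genes shifted by 2.36. The shift of these nuclear loci was 0.22 (bootstrap interval -0.12 to 0.87). Carry-over had been expected to give 1.18 or more, and values under 0.59 had been set to speak against it; 0.22 lies under 0.59, but its interval passes it. The bound of 1.18 was too high, as these loci, being less depleted than the mitochondrial genes, would shift by 0.86 under carry-over. The interval holds that value as it holds 0, so the test cannot decide whether carry-over gave the species difference. As mitochondrial transcripts are not translated by S6-containing ribosomes, the pattern is not read as a species difference in what those ribosomes translate. Only the species split among 35 gave as many loci, with 101 against 99 for the highest other over all loci and 8 against 2 among the abundant loci. A share of 1 of 35 is the smallest these splits can give, and several such tests were run. Over all loci the counts are too close to exclude chance, and among the abundant loci the split argues against it only weakly. With DESeq2 chance cannot be excluded, as 3 of 35 splits called as many (718, against 734).

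The third pattern is that nuclear respiratory chain genes were higher in PC than in MC input. With the trend on locus length removed from the fold changes, 39.5% of the median remained, between the bounds set, so the length trend and a species difference cannot be told apart by it. With each library's own trend removed, PC fish lay above MC fish by 0.81 (0.42 ± 0.27 against -0.39 ± 0.46, SD, n = 4 each; exact permutation p = 0.0286, the smallest of 70 arrangements, adjusted p = 0.114 over 4 lists). The closest fish were MC control fish 22 at 0.06 and PC mirror fish 12 at 0.15. Of 10000 length-matched lists 1 was as high, but random lists do not keep the correlation among members of a list. These values argue only weakly against locus length alone. Locus length runs from start to end in the genome with introns, so transcript length was not tested. Control fish, whose inputs were of similar depth, showed 77.2% of the difference (1.31 of 1.69), which argues against depth alone. In mirror fish, whose PC inputs were deeper, the difference was 2.14, so a part of it from depth stays open. The 30 abundant members scaled to the abundant loci kept 0.85. Species, RNA quality, and the fit of each species to a shared reference stay open as untested, so a species difference in respiratory genes is a hypothesis.

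The ribosomal protein genes in the same inputs behaved otherwise: removing each library's length trend left -0.08 (exact permutation p = 0.8; 6348 of 10000 length-matched lists as high), and scaling to the abundant loci left -0.06. With the length trend removed, neuropeptide genes differed by 0.24 (exact permutation p = 0.143, adjusted p = 0.286; -0.05 in batch a) and translation factors by 0.16 (exact permutation p = 0.314, adjusted p = 0.419). In the inputs alone 1 of 35 splits, the species split, called as many loci (2872, against 1), and likewise for loci with counts in 1 species alone (1 of 35, 190 against 23). The margins of these counts argue against chance. They do not exclude it, as 1 of 35 is the smallest share these splits can give and several such tests were run. Loci with counts in 1 species alone may reflect the fit of each species to the shared reference and not expression, which was not tested. Over all 16 libraries the species split in input called 2 and the highest other 0 (1 of 35), too few calls to decide anything. With DESeq2 only the species split gave as many there (1 of 35), but 37 against 35 is too close to exclude chance.

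For 4 mirror comparisons the real split called 0 loci in edgeR, so that all 35 of 35 splits had to call as many and the count decides nothing. The highest other split called 101 loci for the mirror effect on IP enrichment and for its species difference, 698 for mirror against control in IP (the species split in each case) and 2 in input. These many calls in splits other than the mirror split point to a structure of the fish in IP libraries that does not follow the mirror; a split other than the species split called 99 for IP enrichment, so it is not one of species alone. With DESeq2 chance cannot be excluded, as 19 of 35 splits called as many loci as the mirror split (587, against 734) and 13 of 35 as many as the species difference (613 against 734). The same held for mirror against control in IP (18 of 35; 744 against 1001) and in input (21 of 35; 11 against 37).

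Other values stood far from the rest or differed between groups. The IP library of PC control fish 11 had 14.3% of its counts on the mitochondrial sequence (next 8.15%, lowest 2.94%). The input of MC mirror fish 21 had 9.32% on mitochondrial protein genes (next 7.10%, lowest 5.49%). The median IP minus input of radial glia genes was -3.92 in MC mirror fish 9 (next -1.98, highest -0.64), that of translation factors 1.77 in MC mirror fish 21 (next 0.40, lowest -0.29), and that of hdgfl2 0.15 in PC mirror fish 23 (next 1.69, highest 2.93). Log2 species differences of IP enrichment past the threshold over all loci were at least 10.11 for lg7h18orf32, 9.98 for laptm4a and 8.06 for srgn, and fitted as 4.52 for ND2, 2.66 for ND1 and 2.12 for COX1. Among the abundant loci lg7h18orf32 and srgn passed as well, with the same bounds, and the fitted values were 9.88 for rbp4, 4.19 for ND2, 2.61 for rpl39, 2.38 for ND1 and 1.17 for rps15. The species difference of the mirror effect among the abundant loci was fitted as 5.83 for ND2, and was at least 9.97 for LOC101472582 and 9.64 for LOC101486506 and -8.25 or lower for LOC112433406. These bounds stand for loci at 0 in the IP libraries of a group, and rest on counts and not on molecules.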

How the results depend on the processing

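The added fits of abundant loci, of 1 fraction under each alternative and without both MC fish of batch a were chosen after the data had been seen. Sparse IP libraries limit every comparison that uses them, and with 2 fish per group a fit without 1 fish leaves a lone fish that is assumed to vary like the other groups. For the counts of calls given below, 121 values under alternatives stayed within 1.5 times and 107 did not. For single genes of the text, counts of list calls and the remaining counts, 1759 values kept their direction and side of the threshold or their size, 429 no longer passed, 39 newly passed and 92 moved. These include sign changes of genes that had not passed, such as rps6 for IP against input (0.14, and -0.02 without MC control fish 10). Of the genes of the text that had passed, 0 reversed. Medians of lists are not part of these numbers, and the report gives those that changed sign. Among all named genes, 2 values reversed for IP against input and 37 for PC against MC in the inputs alone. The cause of the changes below was not tested.

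With fish as a replicate block the calls were 181 for IP against input (17095 without it), 4 for the mirror effect on IP enrichment (0), and 4 for its species difference (0). They were 6 in MC (1), 2 in PC (0), 26 for the species difference of IP enrichment (11), 106 for IP against input among abundant loci (199) and 0 for the species difference of IP enrichment among them (15). Among abundant loci the mirror effect, its species difference and the effect in MC also went to 0 (2, 4 and 7). Of the gene list tests the block ended 2 among abundant loci for IP against input (radial glia and translation factors, adjusted p = 0.0562 each) and added skeletal muscle genes for the species difference of IP enrichment over all loci (adjusted p = 0.0363, 0.137 without it); it changed no other list call. The block cannot be fitted to contrasts within a fraction.

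Limma-voom gave 0 for the mirror effect in MC, 425 for PC against MC in input (0 in edgeR), and 136 for the species difference of IP enrichment. It gave 174 for mirror against control in IP (1), and 376 and 54 for IP against input and the species difference among abundant loci. Among these it gave 0 for the mirror effect, its species difference, the effect in MC and mirror against control in IP (2, 4, 7 and 6), where DESeq2 gave 37, 35, 64 and 92 and RLE size factors 0, 3, 6 and 6. DESeq2 gave 1821 for the mirror effect, 1992 for its species difference, 2071 in MC, 1201 in PC, and 115 for PC against MC in input, and 2544 for the species difference of IP enrichment. It gave 2990 and 36 for mirror against control in IP and input, 333 and 101 for the abundant loci, and 5918 for PC against MC in the inputs alone (3000). RLE size factors gave 5 for PC against MC in input. Without a batch term the species difference of IP enrichment had 23.

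Batch a alone gave 7335 for IP against input, 0 for the species difference of IP enrichment, 0 for mirror against control in IP, and 0 and 79 among abundant loci. Batch b alone gave 5136, 0, 0, 80 and 0. Without both MC fish of batch a, IP against input had 4 (8747 at an adjusted p under 0.1), the species difference 1, and the abundant loci 329 and 63.

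Without a low-count filter the mirror effect had 2, its species difference 1, MC 4, PC against MC in input 4, the species difference of IP enrichment 28, mirror against control in IP 3, and PC against MC and mirror against control in the inputs alone 4633 and 272. With at least 10 counts in 8 libraries, IP against input had 9892 and the species difference of IP enrichment 24. At an adjusted p under 0.1 the mirror effect had 1, its species difference 1, the species difference of IP enrichment 24 and, among abundant loci, 30.

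The abundant loci alone gave 199 for IP against input, 2 for the mirror effect, 4 for its species difference, 7 in MC, 6 for PC against MC in input, 6 for mirror against control in IP and 536 for PC against MC in the inputs alone. The 8 libraries of a fraction alone gave 3000 for PC against MC in input, 10 for mirror against control in IP and 3 in input. Of the gene list tests 12 passed over all loci and 0 with an estimated correlation. Fry, which asks whether a list changed and not whether it differed from other loci, passed 26, of which 23 were for IP against input, where all loci had a median of -4.97.

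Over all loci a fit without 1 fish also passes more loci through the filter, so both change together. Leaving out 1 fish gave 9582 to 13532 loci for IP against input, 0 to 1 for the mirror effect and 0 to 1 for its species difference (1 without MC control fish 10 or 22), and 0 to 3 in MC. It gave 0 to 13 for the species difference of IP enrichment, 0 to 4 for mirror against control in IP, 91 to 303 and 0 to 133 for the abundant loci, and 2676 to 5406 for PC against MC in the inputs alone.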

Other observations

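Over all loci, many cell-type and signalling genes were called lower in IP, but so were 16997 of all 29597 loci, with a median log2 fold change of -4.97. Data simulated with the spread measured in each fraction gave 12908 false calls among 12995 for this comparison. The calls below thus do not show that single members were lower. The lists given here did not pass against the other loci. Of these 9 of 11 microglia and macrophage genes were lower in IP (10 adjusted over the list alone; median log2 fold change -6.51, list adjusted p = 0.0507). The same held, with values in the same order, for 16 of 18 fibroblast and meninges genes (16; -6.15, 0.170), 17 of 22 monoamine genes (17; -6.73, 0.226), and 11 of 14 stress axis genes (12; -6.68, 0.0923). Further lists were 6 of 8 social neuropeptide and hormone receptor genes (7; -6.28, 0.797), 9 of 14 steroid receptor and synthesis genes (10; -4.63, 0.757), 15 of 26 immediate early genes (15; -4.62, 0.872) and 13 of 24 neuropeptide genes (13; -4.39, 0.977). In further lists the members lower in IP, the number adjusted over the list alone, the median and the list adjusted p were as follows. They were GABA and glycine neurons (12 of 20 lower; 12; -4.07, 0.861), glutamate neurons (8 of 15; 5; -3.55, 0.977), and oligodendrocytes (7 of 16; 6; -3.42, 0.677). They were chaperones (11 of 23; 11; -3.40, 0.797), synaptic plasticity and calcium signalling (17 of 37; 14; -2.86, 0.757), and skeletal muscle (4 of 8; 4; -2.66, 0.757). Last came red blood cells (3 of 7; 3; -3.59, 0.872), photoreceptor and pineal genes (6 of 10; 6; -5.77, 0.838) and pituitary hormones (3 of 6; 3; -4.15, 0.797).

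Among the abundant loci, IP enrichment changed with the mirror in MC for LOC112433406 (adjusted p = 0.00812) and LOC101472582 (adjusted p = 0.0121). LOC112433406 had 0 counts in both MC control IP libraries and 279 and 657 in MC mirror fish 9 and 21, and LOC101472582 had 363 and 1009 in MC control fish 10 and 22 and 0 in both mirror fish. The transcript of aplp2, an amyloid precursor-like gene, was lower in IP of mirror fish over both species (-4.59 ± 0.83, adjusted p = 0.0432), with 0, 7, 350 and 130 counts in mirror fish and 285, 1583, 583 and 288 in control fish. It did not pass with limma-voom (-4.87), in batch a (-2.14) or batch b alone (-4.19), or without PC control fish 11 or 24 or PC mirror fish 12 or 23, and was at -7.66 without MC mirror fish 21. Limma-voom called 0 abundant loci for mirror against control in IP and for the mirror effect in MC. In input, gabarap, which encodes an autophagy and receptor trafficking protein, was higher in PC (2.43 ± 0.24, adjusted p = 0.00170). Scaled to all tested loci, its level was 10.81 ± 0.22 against 7.81 ± 0.31 log2 CPM (SD, n = 4 each). In the fit of abundant loci gpm6a, of neuronal membranes, was lower in PC (-1.70 ± 0.27, adjusted p = 0.0207). Neither passed in batch a or b alone, and gpm6a did not pass without any 1 of the 4 PC fish or of the MC mirror fish (-1.51 to -1.82).

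In the authors' deposited results, 16229 loci had an adjusted p under 0.05 for IP against input (1443 higher and 14786 lower), of which 12996 were also called with the same sign by edgeR here. Of these loci 303 had counts in all 8 IP libraries. For the mirror effect on IP enrichment there were 782 (307 higher and 475 lower; 0 also called by edgeR and 530 by DESeq2 here; 731 with counts in 4 or fewer IP libraries), and for its species difference 993 (392 and 601; 0 and 836; 801). The authors list fbl at -8.94 (adjusted p = 6.47e-05) and sertm1 at -9.47 (adjusted p = 2.45e-05) for the mirror effect. For its species difference they list wbp4 at 18.56 (adjusted p = 1.91e-06), LOC101486506 at 10.83 (adjusted p = 9.05e-06), ND2 at 6.79 (adjusted p = 0.00555) and npy at 6.55 (adjusted p = 0.0241). In the same list ND1 (2.78, adjusted p = 0.235), COX1 (2.57, adjusted p = 0.236) and ND5 (2.14, adjusted p = 0.447) did not pass. Their values for IP against input were -3.91 for ND5 (adjusted p = 2.84e-07) and 2.90 for chd2 (adjusted p = 4.86e-06).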
